A study of Homo sapiens with 18 samples.

How the data were processed

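RNA was extracted with a column kit that included DNase treatment and made into poly-A selected libraries, per the labels' protocols. The 18 samples were mapped to 6 groups of 3 from their labels, and replicate numbers were taken from the labels. Processed data came as 4 tables, each holding the genes and libraries of a comparison of 2 groups. The authors deposited raw read counts per gene, which are whole numbers and were used for every test here. The same tables hold a signal that the authors made by dividing the counts by a size factor per library, as the deposited values themselves show. They also hold FPKM values per the file headers, log2 fold changes and p-values from the authors' fits. Per the submitters' processing notes, GRCh38 (hg38) was the genome build and DESeq2 was used, with no version given. The aligner, the counting program, the annotation release and the use of strand are not given in the sources used here. All gene identifiers of the tables occur in GENCODE release 29, which gave identical coordinates for 94.3, 100, 94.4 and 94.4% of the genes of the 4 tables. A gene whose exons overlap another gene's by more than 20% was not given values in the text, since reads counted without strand cannot be assigned. Genes with 0 counts in a whole table were left out of it by the authors.

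Total counts per library ranged from 14093399 to 23063491 over the 4 tables, with 0 counts assigned to unnamed features and 0 columns of samples from other series. The iAstro libraries were counted again for the table with the OptoNeurons. The recount gave identical counts for 59.7, 58.7 and 60.2% of 29899 shared genes, and each comparison used the counts of its own table. The tables were normalized separately, and levels across tables were put on one scale by joining the counts of the 27846 genes present in all 4. There the iAstros have their first counting, whereas the OptoNeurons were counted only alongside the recount. Between both countings, 261, 235 and 226 genes of iAstro replicates 1, 2 and 3 differed by over 2-fold. Joined levels and the fit of all 18 libraries therefore mix both countings. No pair of libraries in a group agreed within sampling noise, the lowest chi-square per gene being 2.73.

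Counts as deposited were tested with edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3), with TMM factors, the filterByExpr filter, no covariate, two-sided p-values and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. The change between CNO for 2 d and for 2 h was tested on the 9 Astrostim libraries joined by gene identifier, which is also the test of the difference between both CNO effects. CPM values are counts over library sizes scaled by TMM within the comparison. Where a group had 0 counts of a gene, the fold was computed against a floor of 3 counts over the group, and where it had 1 to 3, the ratio of counts is given with an exact 95% interval, which covers counting error only. Gene lists were tested with camera in limma (version 3.58.1) with its preset correlation of 0.01, adjusted over the lists with at least 5 tested members. Of the 49 lists, 25 passed in iAstros against NPCs, 33 in OptoNeurons against iAstros, 24 after CNO for 2 h, 32 after CNO for 2 d and 23 between the CNO times. With a correlation estimated from the data 0, 0, 6, 0 and 4 passed.

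The groups, the tests, the gene lists, the alternatives and the rule for the genes named were chosen before the data were examined, apart from the additions named at the end. For each comparison the rule took the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with a mean of at least 100 counts and with libraries that did not overlap between the groups. To these it added up to 4 members past the threshold of each list past its test, a member moving against the list, and a fixed set of markers whatever their result. The text names a part of them, and POU5F1 was chosen after its values were seen. Some genes that the rule names are not reported here.

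Samples with the same number deviated together in iAstros against NPCs. The correlations of their deviations from the group means across genes were 0.102, 0.258 and 0.248, each above those with other numbers (−0.278 to 0.0540). The rule that numbers pair samples where every such correlation exceeds 0.1 was just met, so values with the replicate number as a block are given in that comparison where they change a call. The counts with that block had been seen by then, and the labels name no shared batch or day. In the other comparisons the numbers did not pair the samples.

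The alternatives tried were size factors by the RLE method, no filter on low counts, a stricter filter of at least 50 counts in 3 libraries, DESeq2 (version 1.42.0), limma-voom, the replicate number as a block, leaving out each library, all 18 libraries in one fit, a minimum absolute log2 fold change of 1, camera with an estimated correlation, and fry. A pseudocount and recovered reads were not needed, since the files hold counts. Added after the data were seen were a correction for gene length and GC content and the block in DESeq2 and limma-voom. The overlap of the CNO calls was set beside 100 simulated draws of unchanged groups. The controls were simulated as well, once per draw, and shared by both comparisons, with each gene drawn independently. Each test was checked on simulated counts with 200 changed genes, 50 at each of 4 fold sizes. At changes of 2-, 4-, 16- and 64-fold it recovered 0, 12, 78 and 88% of them in iAstros against NPCs (17441 genes), 2, 58, 96 and 100% in OptoNeurons against iAstros (18040 genes), 20, 92, 100 and 100% after CNO for 2 h (17077 genes), 98, 100, 100 and 100% after CNO for 2 d (17023 genes), and 64, 98, 100 and 100% between the CNO times (17617 genes). In the same order it called 5, 16, 7, 8 and 13 unchanged genes. Genes were drawn independently here too, with no deviation shared across the genes of a library. These rates therefore do not cover libraries that stand apart over many genes.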

Results

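Gene expression was measured by sequencing of polyadenylated RNA from 18 samples of cells derived from WT-C11, an established human pluripotent stem cell line, and grown as monolayers on a basement membrane coating. The samples formed 6 groups of 3: neural progenitor cells (NPCs) at day 12 without doxycycline, iAstros at day 12 with doxycycline, OptoNeurons at day 14 with doxycycline, and chemogenetic iAstros (Astrostim cells) at day 14 with doxycycline, without or with clozapine N-oxide (CNO) for 2 h or 2 d. Doxycycline switches on inducible transgenes, and CNO is a ligand of engineered receptors used to activate chosen cells. The stated purpose was to characterise the identity of the neural subtypes and the consequence over time of activating Gq signalling in astrocytes. In the coordinates the tables give, on GRCh38 per the submitters' processing notes, NEUROG2 lies on chromosome 4 from 112513516 to 112516172, SOX9 on chromosome 17 from 72121020 to 72126420, NFIA on chromosome 1 from 60865259 to 61462793, and CHRM3 on chromosome 1 from 239386565 to 239915452. Total counts per library ranged from 14093399 to 23063491 reads over the tables tested. The labels number the samples of a group but do not say that they were separate cultures, so p-values measure only the spread between these libraries, which may be technical. For NEUROG2, NFIA, SOX9 and CHRM3, reads of a transgene and of the resident gene could not be told apart.

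The comparison of iAstros with NPCs addressed how the doxycycline-treated cells differed from the progenitors at day 12. Astrocyte genes stood among those that were higher in iAstros than in NPCs, and LIN28A among the 7 genes that were lower. The pan-neuronal and glutamatergic lists also passed camera, but not without iAstro replicate 2 (adjusted p = 0.105 and 0.0914) or with an estimated correlation. The neuronal markers MAP2, DCX and SLC17A6 differed by 2.74 ± 0.68, 2.32 ± 1.16 and 5.02 ± 1.60, and the progenitor factor SOX1 by 7.54 ± 1.51. These 4 genes missed the threshold in edgeR (adjusted p = 0.119, 0.317, 0.169 and 0.0852). MAP2, SLC17A6 and SOX1 passed in DESeq2 (adjusted p = 0.00167, 0.00392 and 8.43e-08). All 4 passed in DESeq2 with the replicate block (adjusted p = 1.35e-07, 1.10e-04, 2.54e-04 and 1.68e-23). They also passed with all 18 libraries in one fit (adjusted p = 0.00109, 0.0407, 0.00157 and 1.07e-04). SOX1 further passed without a filter on low counts (adjusted p = 0.0489) and in limma-voom with the replicate block (adjusted p = 0.0478). ALDH1L1, a folate enzyme used as an astrocyte marker, rose by a log2 fold change of 5.33 ± 0.67 (SE, adjusted p = 0.0416), and BCAN, which encodes the brain matrix proteoglycan brevican, rose by 6.77 ± 0.90 (adjusted p = 0.046), from 1.73 ± 1.51 to 190 ± 111 CPM (mean ± SD, n = 3). LIN28A, which encodes an RNA-binding protein of pluripotent and early progenitor cells, fell by 6.44 ± 0.78 on the log2 scale (adjusted p = 0.0399), from 1676 ± 799.6 to 19.3 ± 15.4 CPM. Of 17441 genes tested, 72 passed the threshold, 65 higher and 7 lower in iAstros, and 0 passed with the replicate number as a block, where the adjusted p was 0.0732 for ALDH1L1, 0.0954 for BCAN and 0.0730 for LIN28A.

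Of the 36 astrocyte markers measured, 2 rose, none fell and 34 did not pass the gene test, whereas 23 were higher and 2 lower when adjusted over the list alone. Their median log2 fold change was 2.65 (adjusted p = 7.01e-10 for the list, adjusted p = 0.428 with an estimated correlation). The other member past the threshold was MLC1, a membrane protein of astrocyte endfeet, at 7.28 ± 0.99 (adjusted p = 0.046, but adjusted p = 0.0551 with the replicate block). S100B, a calcium-binding astrocyte protein, averaged 234 ± 140 CPM in iAstros and 3.82 ± 2.89 CPM in NPCs, a log2 difference of 5.94 ± 0.92 that missed the threshold (adjusted p = 0.055). S100B passed without NPC replicate 3 (adjusted p = 0.0409), without a filter on low counts (adjusted p = 0.0230), with the stricter filter (adjusted p = 0.0489), in DESeq2 (adjusted p = 2.60e-11), in DESeq2 and limma-voom with the replicate block (adjusted p = 4.62e-16 and 0.0495) and with all 18 libraries in one fit (adjusted p = 4.03e-05). GFAP, the astrocyte intermediate filament, and AQP4, the water channel of astrocyte endfeet, differed by 5.26 ± 1.23 and 5.29 ± 1.24 (adjusted p = 0.108 for each). Both passed in DESeq2 (adjusted p = 3.48e-05 and 3.69e-05), in DESeq2 with the replicate block (adjusted p = 8.15e-10 and 1.02e-10) and with all 18 libraries in one fit (adjusted p = 7.62e-04 and 7.44e-04), and AQP4 also without NPC replicate 3, at 7.38 (adjusted p = 0.0430). The glutamate transporter SLC1A3 lay at 129 ± 54.2 CPM in iAstros and 84.8 ± 26.3 CPM in NPCs (adjusted p = 0.425).

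Of the 20 early glial transcription factors, 0 passed edgeR's quasi-likelihood test over all genes, and 7 were higher and 2 lower when adjusted over the list alone. Their median was 1.19 (adjusted p = 0.0181 for the list, adjusted p = 0.588 with an estimated correlation). The list missed the threshold without iAstro replicate 3 (adjusted p = 0.0534). NFIA, a factor that starts astrocyte formation in the developing nervous system, averaged 722 ± 262 CPM in iAstros and 8.15 ± 8.64 CPM in NPCs, a log2 difference of 6.47 ± 0.92 (adjusted p = 0.0516). NFIA passed without NPC replicate 3, at 7.82 (adjusted p = 0.0167), without a filter on low counts (adjusted p = 0.0167), with the stricter filter (adjusted p = 0.0423), in DESeq2 and limma-voom (adjusted p = 1.20e-13 and 0.0448), in both with the replicate block (adjusted p = 4.01e-37 and 0.0478) and with all 18 libraries in one fit (adjusted p = 1.79e-05). SOX9, its partner in glial specification, averaged 585 ± 223 and 217 ± 171 CPM (adjusted p = 0.403). Among the 28 neural progenitor genes, 0 rose and 1, LIN28A, fell, against 12 higher and 2 lower when adjusted over the list alone. The list had a median of 1.52 (adjusted p = 5.37e-04, adjusted p = 0.588 with an estimated correlation).

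Of the 11 pluripotency genes, 1 fell and 10 did not pass, and 7 were lower when adjusted over the list alone. As a group they had a median of −4.73 (adjusted p = 1.46e-04, adjusted p = 0.588 with an estimated correlation). NPC replicate 3 stood apart in this group of genes. It held 15 of the 16 members present in the tables above 10 CPM, against 7 in each of NPC replicates 1 and 2. Its genome-wide counts had a Spearman correlation across genes of 0.848 and 0.836 with those of the other NPC libraries, which correlated with each other at 0.966. Of the 40 cell cycle genes, 0 passed edgeR's quasi-likelihood test over all genes, and 25 were lower when adjusted over the list alone. For the list, the median was −1.51 (adjusted p = 4.44e-18, adjusted p = 0.588 with an estimated correlation). MKI67, a marker of dividing cells, differed by −0.89 ± 0.66 (adjusted p = 0.488).

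The other genes past the threshold included ABCA8, a lipid transporter, which rose by 8.38 ± 1.01 (adjusted p = 0.0399), and ADGRG1, an adhesion receptor of neural progenitors and glia, which rose from 7.75 ± 5.7 to 468 ± 31.7 CPM (adjusted p = 0.0487). APOL4, an apolipoprotein L gene, had 0 counts in the NPC libraries and was at least 269-fold higher in iAstros, with the floor set at 3 counts over the group (adjusted p = 0.046). LAMA4, a laminin chain of basement membranes, rose by 4.89 ± 0.41 (adjusted p = 0.0397), CNR1, the cannabinoid receptor of neurons and glia, by 6.20 ± 0.67 (adjusted p = 0.0399), and IFI44L, an interferon-induced gene, by 5.85 ± 0.71 (adjusted p = 0.0399). Besides LIN28A, the genes that fell included OTX2, a forebrain and midbrain patterning factor (−4.41 ± 0.54, adjusted p = 0.0403), the transcription factor GATA2 (−5.80 ± 0.70, adjusted p = 0.0399) and ROR2, a WNT receptor (−3.01 ± 0.41, adjusted p = 0.046). With the replicate number as a block these calls ended, at an adjusted p of 0.0698 for ABCA8, 0.0765 for ADGRG1, 0.0876 for APOL4, 0.0657 for LAMA4 and for IFI44L, 0.0551 for CNR1 and for ROR2, 0.0730 for OTX2 and 0.0732 for GATA2. The libraries of the groups did not overlap in 4982 genes, 28.6% of those tested, where chance gives 10%.

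The calls of this comparison depended on single libraries and on the model. With the replicate number as a block, edgeR's quasi-likelihood test called 0 genes (3399 at an unadjusted p under 0.05), and DESeq2 and limma-voom called 2206 and 151 with the block and 1972 and 77 without it. The edgeR test called 0 genes without iAstro replicate 1 (1977 at an unadjusted p under 0.05), NPC replicate 1 (3033) or NPC replicate 2 (2958), 1 without iAstro replicate 3, 119 without iAstro replicate 2 and 293, among them 67 of the 72, without NPC replicate 3; DESeq2 and limma-voom were not run with libraries left out.

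OptoNeurons and iAstros were compared to set the induced neurons against the astrocytes; day and cell type went together, since OptoNeurons were collected at day 14 and iAstros at day 12. At the preset correlation, the list of pan-neuronal genes passed as higher in OptoNeurons, and those of astrocyte, cell cycle and extracellular matrix genes as lower. With an estimated correlation no list passed. NEUROG2, a proneural factor widely used to turn stem cells into neurons, averaged 915 ± 66.8 CPM in OptoNeurons and 11.4 ± 16.8 CPM in iAstros (log2 fold change 6.33 ± 1.49, adjusted p = 0.0136). SOX9 and NFIA fell by 10.20 ± 0.62 and 8.06 ± 0.49 (adjusted p = 3.02e-04 for both), SOX9 from 587 ± 235 to 0.488 ± 0.319 CPM. Of 18040 genes tested, 8465 passed the threshold, 3769 higher and 4696 lower in OptoNeurons.

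Of the 40 pan-neuronal genes, 33 rose and none fell, with 33 higher and 1 lower when adjusted over the list alone. Members had a median of 3.88 (adjusted p = 2.43e-11, adjusted p = 0.435 with an estimated correlation). NEFL, a neurofilament subunit, rose from 152 ± 37.2 to 2128 ± 89.4 CPM (adjusted p = 3.31e-04). Of the 34 genes of the presynaptic vesicle machinery, 30 rose and none fell, and 32 were higher and 1 lower when adjusted over the list alone. Taken over all members, the median was 3.27 (adjusted p = 4.28e-12, adjusted p = 0.435 with an estimated correlation). Among them was SYT1, the calcium sensor of transmitter release, at 4.12 ± 0.46 (adjusted p = 9.81e-04).

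Of the 22 proneural transcription factors, 10 rose, 2 fell and 10 did not pass, with the same 10 and 2 counts when adjusted over the list alone. Across the list the median was 1.74 (adjusted p = 5.34e-04, adjusted p = 0.551 with an estimated correlation). NEUROD2, a target of NEUROG2, rose by 7.49 ± 0.91 (adjusted p = 0.00132). Of the 20 glutamatergic genes, 11 rose and 2 fell, with 11 and 2 again when adjusted over the list alone. Their median was 1.96 (adjusted p = 0.00112 for the list, adjusted p = 0.435 with an estimated correlation). The vesicular glutamate transporters SLC17A6 and SLC17A7 rose by 5.25 ± 1.10 (adjusted p = 0.00893) and 6.96 ± 0.38 (adjusted p = 3.02e-04). Of the 9 GABAergic genes, 1 rose and 3 fell, as when adjusted over the list alone, and the list did not pass (median −0.81, adjusted p = 0.774). Of the 18 sensory and peripheral neuron genes, 14 rose and none fell, and 15 were higher and 1 lower when adjusted over the list alone. The list had a median of 4.64 (adjusted p = 2.10e-06, adjusted p = 0.435 with an estimated correlation). Among them were POU4F2 and ISL2, factors of sensory and retinal neurons (7.08 ± 1.17, adjusted p = 0.00364, and 5.95 ± 0.45, adjusted p = 3.77e-04), and SCN9A, a sodium channel of peripheral neurons (2.73 ± 0.19, adjusted p = 3.31e-04).

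Of the 36 astrocyte markers, 33 fell and 1 rose, with 33 and 1 when adjusted over the list alone. As a group they had a median of −5.49 (adjusted p = 2.43e-11, adjusted p = 0.374 with an estimated correlation). FGFR3, a receptor of radial glia and astrocytes, fell by 7.96 ± 0.55 (adjusted p = 3.31e-04), SLC1A3 by 7.93 ± 0.49 (adjusted p = 3.02e-04) and S100B by 7.72 ± 0.72 (adjusted p = 5.98e-04). GFAP fell by 5.86 ± 1.05 (adjusted p = 0.00488), a call that limma-voom did not make (adjusted p = 0.0572). Of the 40 cell cycle genes, 38 fell and none rose, and 39 were lower when adjusted over the list alone. For the list, the median was −4.49 (adjusted p = 1.45e-13, adjusted p = 0.435 with an estimated correlation). MKI67 fell by 8.75 ± 1.27 (adjusted p = 0.00236) and TOP2A, the topoisomerase of dividing cells, by 7.02 ± 0.66 (adjusted p = 6.12e-04). Of the 28 neural progenitor genes, 19 fell and 2 rose, with 19 and 2 when adjusted over the list alone. Members had a median of −4.27 (adjusted p = 5.40e-05, adjusted p = 0.435 with an estimated correlation). NOTCH1, the receptor that holds progenitors undifferentiated, fell by 7.45 ± 0.41 (adjusted p = 3.02e-04) and SOX2, a factor of stem and progenitor cells, by 3.95 ± 0.34 (adjusted p = 4.87e-04), whereas LIN28A rose by 2.88 ± 0.54 (adjusted p = 0.00581).

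Of the 45 extracellular matrix genes, 43 fell and none rose, and 44 were lower when adjusted over the list alone. Taken over all members, the median was −6.47 (adjusted p = 1.45e-13, adjusted p = 0.435 with an estimated correlation). The fibrillar collagen gene COL5A1 fell by 7.15 ± 0.52 (adjusted p = 3.55e-04). COL1A1, the main collagen of fibroblasts, averaged 3576 ± 5236 CPM in iAstros, an SD above its mean, and fell by 13.11 ± 2.35 (adjusted p = 0.00494, but adjusted p = 0.0665 in limma-voom). Of the 24 cholesterol synthesis genes, 21 rose and none fell, with 21 when adjusted over the list alone (median 1.06, adjusted p = 6.12e-08, adjusted p = 0.435 with an estimated correlation), among them the mevalonate pathway enzyme MVD at 2.10 ± 0.21 (adjusted p = 7.91e-04). The edgeR test called 5574 genes without OptoNeuron replicate 1 and 5537 without OptoNeuron replicate 3. The libraries of the groups did not overlap in 10970 genes, 60.8% of those tested, where chance gives 10%.

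**Figure D1:**
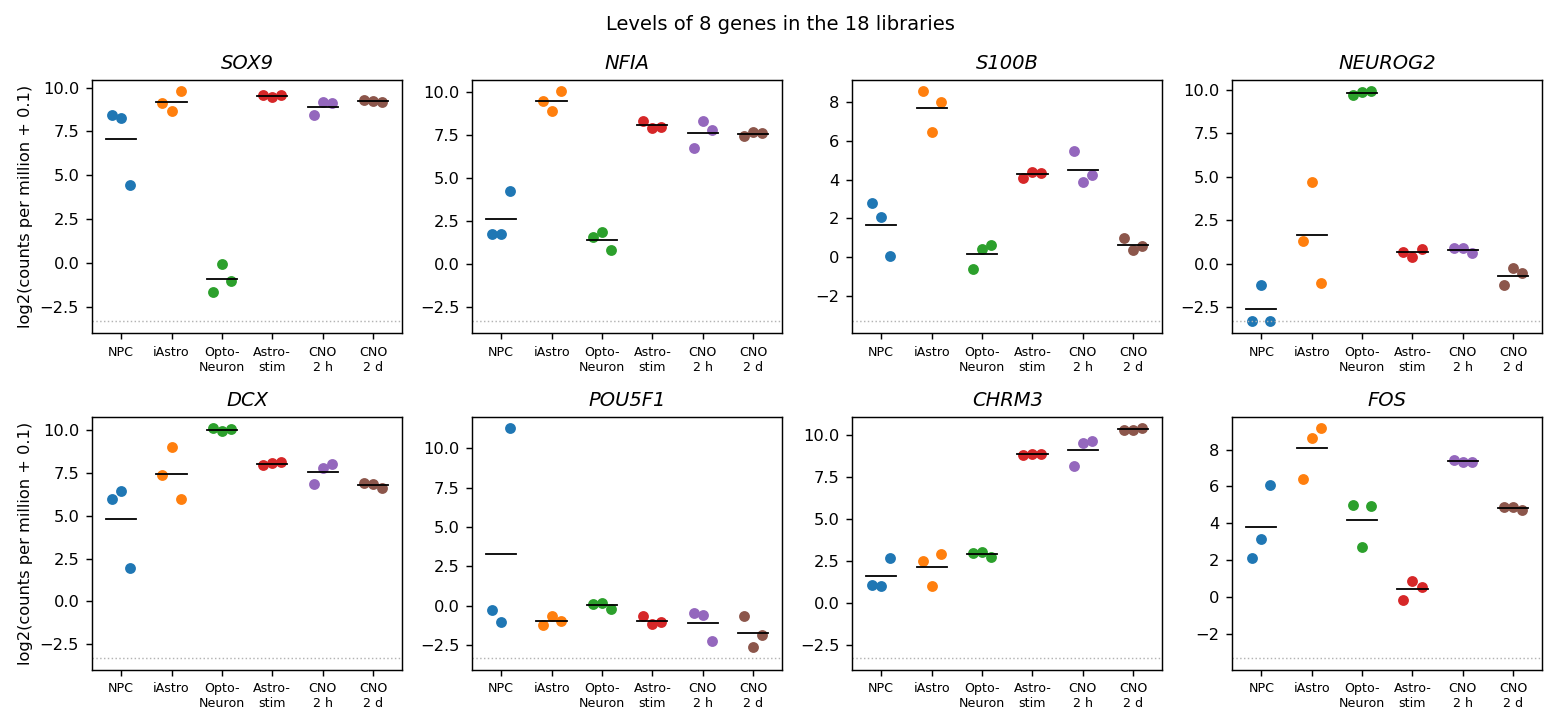
Levels of 8 genes in the 18 libraries, as log2(CPM + 0.1) on one scale for all libraries, with a point per library, a line at the mean of the log values of each group and a dotted line at 0 counts. NEUROG2 is highest in the OptoNeuron libraries, CHRM3 in the Astrostim libraries and POU5F1 in NPC replicate 3, at 2444 CPM. The OptoNeuron libraries were counted alongside the recount of the iAstros, whose first counting is shown.

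Astrostim cells given CNO for 2 h were compared with Astrostim cells without CNO to show the early consequence of CNO. Only Astrostim cells were given CNO, so at 2 h and 2 d effects of CNO itself could not be told apart from those of the engineered receptor. The lists of immediate early genes, feedback regulators of MAP kinase signalling and cytokine genes passed as higher after CNO. FOS, a subunit of the AP-1 factor, rose from 1.33 ± 0.485 to 169 ± 12.7 CPM (mean ± SD, n = 3; log2 fold change 6.99 ± 0.30, adjusted p = 9.96e-05), and the orphan nuclear receptor gene NR4A1 rose from 4.77 ± 0.248 to 396 ± 13.5 CPM (6.37 ± 0.16, adjusted p = 2.44e-05). Of 17077 genes tested, 416 passed the threshold, 379 higher and 37 lower (91.1% higher, against 61.7% without CNO 2 h replicate 1), and 329 of the higher and 22 of the lower had an absolute log2 fold change of at least 1. CHRM3, the muscarinic receptor gene from which common Gq-coupled designer receptors were made, lay at 475 ± 10.1 CPM without CNO and 622 ± 277 CPM after 2 h (adjusted p = 0.608, but a rise of 0.72 with adjusted p = 1.04e-08 without CNO 2 h replicate 1), against 3.2 ± 2.33 CPM in NPCs and 4.77 ± 2.65 CPM in iAstros in a table normalized separately.

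Of the 35 immediate early genes, 31 rose and none fell, and 34 were higher when adjusted over the list alone. Across the list the median was 3.49 (adjusted p = 7.15e-61, adjusted p = 0.00486 with an estimated correlation). EGR1, a zinc finger factor induced by growth signals, rose by 5.97 ± 0.18 (adjusted p = 4.06e-05) and FOSB, a partner of JUN proteins, by 7.02 ± 0.27 (adjusted p = 7.88e-05). NPAS4, a factor induced by calcium influx in neurons, rose by 6.01 ± 0.18 (adjusted p = 4.06e-05). The count ratio of EGR3 was 2271 (95% counting interval 628 to 18756), from 2 counts over the 3 control libraries. ARC, a synaptic gene induced by activity, rose by 1.82 ± 0.17 (adjusted p = 0.00221). Of the 22 MAP kinase feedback genes, 15 rose and none fell, and 20 were higher and 1 lower when adjusted over the list alone. Their median was 1.72 (adjusted p = 5.65e-28 for the list, adjusted p = 0.00682 with an estimated correlation). The MAP kinase phosphatases DUSP1 and DUSP5 rose by 3.33 ± 0.18 (adjusted p = 2.33e-04) and 5.55 ± 0.29 (adjusted p = 2.13e-04), and the ephrin receptor EPHA2 by 3.86 ± 0.14 (adjusted p = 7.88e-05). Of the 25 targets of calcium-NFAT and CREB signalling, 14 rose and none fell, and 21 were higher when adjusted over the list alone. The list had a median of 1.32 (adjusted p = 1.46e-25, adjusted p = 0.00662 with an estimated correlation). RCAN1, a calcineurin inhibitor induced by calcineurin itself, rose from 45.2 ± 5.37 to 475 ± 30.9 CPM (adjusted p = 1.16e-04).

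Of the 15 cytokine and chemokine genes, 9 rose and none fell, and 11 were higher when adjusted over the list alone. As a group they had a median of 2.31 (adjusted p = 6.90e-17, adjusted p = 0.0388 with an estimated correlation). CXCL8, the neutrophil chemokine interleukin 8, had 0 counts in the control libraries and was at least 345-fold higher (20 ± 3.29 CPM, adjusted p = 6.61e-04). CCL2, which recruits monocytes, rose by 6.50 ± 0.51 (adjusted p = 9.37e-04). LIF, a cytokine that drives astrocyte differentiation, had a count ratio of 430 (95% counting interval 119 to 3561) from 2 control counts. Of the 23 NF-kB targets, 13 rose and none fell, and 15 were higher when adjusted over the list alone (median 1.49, adjusted p = 2.44e-17, adjusted p = 0.0326 with an estimated correlation), with the NF-kB subunit RELB at 5.67 ± 0.39 (adjusted p = 5.64e-04). Of the 21 contractile genes and targets of YAP and SRF, 11 rose and none fell, and 19 were higher when adjusted over the list alone. For the list, the median was 1.60 (adjusted p = 5.55e-21, adjusted p = 0.0621 with an estimated correlation). CCN2, listed under its older symbol CTGF, a matrix-associated growth regulator, rose from 48.5 ± 16.6 to 1672 ± 143 CPM (adjusted p = 3.01e-04), and SRF, the factor that binds serum response elements, rose by 2.04 ± 0.14 (adjusted p = 5.96e-04). Of the 28 growth and neurotrophic factors, 5 rose and none fell, and 11 were higher and 1 lower when adjusted over the list alone. Members had a median of 0.39 (adjusted p = 4.02e-04, adjusted p = 0.0642 with an estimated correlation). PDGFB, a platelet-derived growth factor chain, rose by 4.21 ± 0.20 (adjusted p = 1.28e-04).

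Genes that fell after 2 h included BCL11B, a zinc finger factor (−2.51 ± 0.24, adjusted p = 0.00221), TXNIP, an inhibitor of thioredoxin (−1.61 ± 0.13, adjusted p = 9.90e-04), and ZIC1, a factor of dorsal neural tissue and neural crest (−1.50 ± 0.13, adjusted p = 0.0014). Of the 15 neural crest and Schwann cell genes, 1 rose and 1 fell, and 1 was higher and 5 lower when adjusted over the list alone. Taken over all members, the median was −0.35 (adjusted p = 0.00325, adjusted p = 0.195 with an estimated correlation). The member that rose was SNAI2, a factor of migrating crest cells (1.72 ± 0.12, adjusted p = 5.97e-04). The 31 astrocyte markers held 1 gene that rose, also when adjusted over the list alone, and 30 that did not pass (median 0.14, adjusted p = 0.411 for the list). Some astrocyte genes lay near the floor in Astrostim cells without CNO, with GFAP at 0.323 and AQP4 at 0.0930 CPM on the scale of all libraries. SLC1A3 lay at 100 CPM there.

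CNO 2 h replicate 1 stood apart from the other CNO 2 h and control libraries. Ribosomal protein genes took 10.7% of its reads and 4.42 to 5.52% of the reads of those libraries, and its counts correlated at 0.936 and 0.940 with those of CNO 2 h replicates 2 and 3 across genes (Spearman), which correlated at 0.994. The list of 40 ribosomal proteins passed as higher after 2 h (median 0.61, adjusted p = 4.84e-04), although 0 of its genes passed edgeR's quasi-likelihood test over all genes or when adjusted over the list alone, and with an estimated correlation its adjusted p = 0.593. Without replicate 1 it pointed the other way (adjusted p = 0.578). The 31 nuclear genes of oxidative phosphorylation also passed as higher, with 0 past that test over all genes or when adjusted over the list alone (median 0.56, adjusted p = 0.00192, adjusted p = 0.582 with an estimated correlation) and pointed the other way without replicate 1 (adjusted p = 0.982).

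The edgeR test called 3336 genes, 2057 higher and 1279 lower, among them all 416, without CNO 2 h replicate 1, 263 and 259 without CNO 2 h replicates 2 and 3, and 163, 166 and 157 without Astrostim replicates 1, 2 and 3; DESeq2 called 905. With all 18 libraries in one fit it called 155, and ARC, BCL11B, SNAI2, TXNIP and ZIC1 were among the genes then not past the threshold (adjusted p = 0.562, 0.431, 0.613, 0.162 and 0.614). The libraries of the groups did not overlap in 4593 genes, 26.9% of those tested, where chance gives 10%.

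Astrostim cells given CNO for 2 d were compared with the same controls to show the later consequence. At the preset correlation, the lists of endoplasmic reticulum chaperones, amino acid stress genes and growth factors passed as higher than in the controls. Those of WNT target, neural crest, pan-neuronal and ribosomal protein genes passed as lower. No list passed with an estimated correlation. HSPA5, the main chaperone of the endoplasmic reticulum, rose from 688 ± 27.9 to 3265 ± 87.1 CPM (mean ± SD, n = 3; log2 fold change 2.25 ± 0.06, adjusted p = 5.79e-22). A2M, a protease inhibitor, rose from 11.9 ± 0.302 to 499 ± 13.2 CPM (adjusted p = 8.67e-28), and NPTX1, a neuronal pentraxin, fell by 4.64 ± 0.07 (adjusted p = 2.99e-26), from 367 ± 17.1 to 14.7 ± 1.06 CPM. Of 17023 genes tested, 10739 passed the threshold, 5455 higher and 5284 lower, and 1339 of the higher and 1592 of the lower had an absolute log2 fold change of at least 1.

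All 20 genes of the list of endoplasmic reticulum chaperones and the unfolded protein response rose, as they did when adjusted over the list alone. Across the list the median was 1.65 (adjusted p = 8.23e-17, adjusted p = 0.0736 with an estimated correlation). XBP1, the factor that induces many of them, rose by 2.09 ± 0.06 (adjusted p = 4.64e-21). Of the 27 genes of the amino acid stress response, 25 rose and 1 fell, with 25 and 1 when adjusted over the list alone. Their median was 1.27 (adjusted p = 1.33e-12 for the list, adjusted p = 0.0736 with an estimated correlation). STC2, a secreted glycoprotein induced by stress, rose by 5.04 ± 0.10 (adjusted p = 2.61e-24) and TRIB3, a pseudokinase induced by ATF4, by 2.60 ± 0.09 (adjusted p = 4.92e-19). All 15 heat shock genes rose, also when adjusted over the list alone (median 1.08, adjusted p = 1.22e-08, adjusted p = 0.0736 with an estimated correlation), with the chaperone HSPH1 at 1.62 ± 0.06 (adjusted p = 5.98e-19).

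Of the 32 immediate early genes, 25 rose and 5 fell, with 26 and 5 when adjusted over the list alone. The list had a median of 2.10 (adjusted p = 2.31e-09, adjusted p = 0.0736 with an estimated correlation). FOS rose by 4.47 ± 0.16 (adjusted p = 7.25e-19), and ARC fell by 1.57 ± 0.16 (adjusted p = 3.12e-09). Of the 21 MAP kinase feedback genes, 19 rose and 1 fell, with 19 and 1 when adjusted over the list alone (median 2.08, adjusted p = 3.62e-12, adjusted p = 0.0736 with an estimated correlation), including SPRY4, an inhibitor of receptor tyrosine kinase signalling (5.24 ± 0.12, adjusted p = 7.19e-23). Of the 28 growth and neurotrophic factors, 17 rose and 5 fell, with 17 and 6 when adjusted over the list alone. As a group they had a median of 1.33 (adjusted p = 4.19e-05, adjusted p = 0.0736 with an estimated correlation). PDGFB rose by 5.67 ± 0.10 (adjusted p = 4.06e-25) and TGFB1, the ligand that drives matrix production in many tissues, by 3.13 ± 0.09 (adjusted p = 2.12e-20). Of the 46 extracellular matrix genes, 34 rose and 9 fell, with 34 and 9 when adjusted over the list alone. For the list, the median was 0.88 (adjusted p = 2.16e-07, adjusted p = 0.106 with an estimated correlation). The collagen gene COL12A1 rose by 4.08 ± 0.12 (adjusted p = 2.75e-20), and HAS2, a hyaluronan synthase, fell by 2.52 ± 0.13 (adjusted p = 3.37e-15). Of the 12 cytokine and chemokine genes, 9 rose and 2 fell, with 9 and 2 when adjusted over the list alone (median 2.89, adjusted p = 5.29e-04, adjusted p = 0.0758 with an estimated correlation), and CXCL8 was at least 30.8-fold higher than its 0 control counts allow. TFPI2, an inhibitor of matrix proteases, and IL4R, an interleukin receptor, rose by 7.002 ± 0.10 (adjusted p = 2.96e-27) and 6.14 ± 0.12 (adjusted p = 2.22e-24).

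Of the 15 WNT targets, 12 fell and 2 rose, with 12 and 2 when adjusted over the list alone. Members had a median of −1.25 (adjusted p = 5.64e-05, adjusted p = 0.134 with an estimated correlation). APCDD1, an inhibitor of WNT signalling induced by the pathway, fell by 2.49 ± 0.07 (adjusted p = 3.82e-21), and the WNT target SP5 fell by 4.73 ± 0.20 (adjusted p = 1.82e-17). The ligand gene WNT1 fell by 3.94 ± 0.16 (adjusted p = 1.47e-17). Of the 15 neural crest and Schwann cell genes, 10 fell and 4 rose, with 10 and 4 when adjusted over the list alone (median −0.68, adjusted p = 0.00551, adjusted p = 0.132 with an estimated correlation), with FOXD3, a crest factor, at −2.44 ± 0.09 (adjusted p = 5.89e-19). Of the 38 pan-neuronal genes, 28 fell and 5 rose, with 29 and 5 when adjusted over the list alone (median −0.42, adjusted p = 1.05e-05, adjusted p = 0.0736 with an estimated correlation), and of the 32 voltage-gated channel genes, 23 fell and 1 rose, with 23 and 2 when adjusted over the list alone. Taken over all members, the median was −0.63 (adjusted p = 6.75e-06, adjusted p = 0.137 with an estimated correlation). CACNA1A, a calcium channel of nerve terminals, fell by 1.74 ± 0.07 (adjusted p = 1.34e-17). Of the 40 ribosomal proteins, 34 fell and 1 rose, with 34 and 1 when adjusted over the list alone. Across the list the median was −0.34 (adjusted p = 2.83e-06, adjusted p = 0.456 with an estimated correlation).

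The 32 astrocyte markers moved both ways at 2 d: 13 rose and 16 fell, with 13 and 17 when adjusted over the list alone, and the list did not pass (median −0.25, adjusted p = 0.433). CD44, a hyaluronan receptor raised in reactive astrocytes, rose by 1.17 ± 0.22 (adjusted p = 3.79e-05) from a low level, 1.98 ± 0.243 to 4.45 ± 0.245 CPM, and SPARCL1, a matrix protein made by astrocytes, fell by 3.79 ± 0.16 (adjusted p = 5.18e-17). CHRM3 rose by 1.504 ± 0.05 (adjusted p = 9.92e-19), from 481 ± 10.5 to 1365 ± 40.1 CPM. With all 18 libraries in one fit, 974 genes passed, and ARC, CD44, CHRM3 and TRIB3 were among those that did not (adjusted p = 0.236, 0.598, 0.0736 and 0.0877). The libraries of the groups did not overlap in 11382 genes, 66.9% of those tested, where chance gives 10%.

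**Figure D2:**
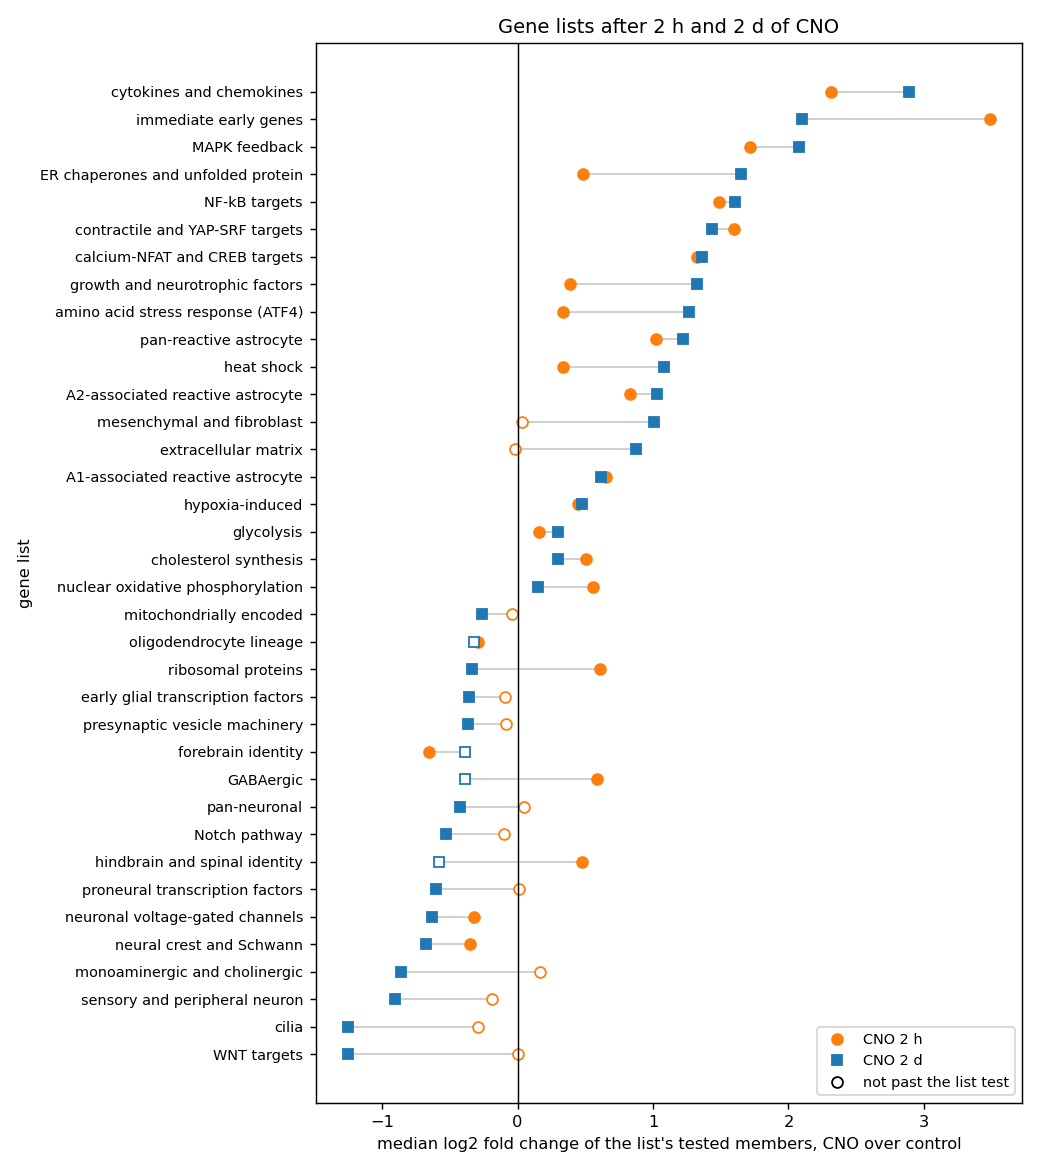
Median log2 fold change against Astrostim cells without CNO of the tested members of 36 gene lists, after CNO for 2 h (circles) and 2 d (squares), with open symbols for lists not past the list test. Immediate early genes have medians of 3.49 at 2 h and 2.10 at 2 d, and endoplasmic reticulum chaperones of 0.48 and 1.65.

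The change over time was tested directly between CNO for 2 d and for 2 h, in one fit of the 9 Astrostim libraries. The lists of immediate early and pan-neuronal genes passed as lower at 2 d than at 2 h, and those of the unfolded protein response and amino acid stress as higher. EGR3 fell from 84.1 ± 9.65 CPM at 2 h to 0.335 ± 0.116 CPM at 2 d (log2 fold change −7.92 ± 0.32, adjusted p = 1.43e-06), while IL4R rose from 2.91 ± 0.052 to 77.8 ± 3.87 CPM (4.74 ± 0.13, adjusted p = 2.52e-07). Of 17617 genes tested, 4672 passed, 2209 higher and 2463 lower at 2 d. The libraries of the groups did not overlap in 7742 genes, 43.9% of those tested, where chance gives 10%.

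Of the 35 immediate early genes, 30 were lower and 1 higher at 2 d, with 30 and 2 when adjusted over the list alone. Their median was −1.75 (adjusted p = 1.52e-19 for the list, adjusted p = 0.0108 with an estimated correlation). FOS fell by 2.52 ± 0.19 (adjusted p = 2.74e-05), NR4A1 by 2.71 ± 0.11 (adjusted p = 1.43e-06) and BTG2, an antiproliferative gene, by 3.42 ± 0.11 (adjusted p = 8.42e-07). Of the 24 NF-kB targets, 10 were lower and 2 higher, with 13 and 4 when adjusted over the list alone. The list had a median of −0.57 (adjusted p = 0.00543, adjusted p = 0.115 with an estimated correlation), while its medians against the controls were 1.49 at 2 h and 1.61 at 2 d. CCL2 fell by 4.28 ± 0.37 (adjusted p = 6.14e-05) and TNFAIP3, an inhibitor of NF-kB signalling, by 2.40 ± 0.21 (adjusted p = 7.72e-05). The lists of MAP kinase feedback genes (6 higher, 8 lower and 8 not past, with 7 higher and 8 lower when adjusted over the list alone, median 0.04, adjusted p = 0.779) and of cytokines (5 higher, 8 lower and 4 not past, with 5 higher and 9 lower when adjusted over the list alone, median −1.12, adjusted p = 0.23) did not pass. Of the 38 pan-neuronal genes, 19 were lower and 2 higher, with 22 and 2 when adjusted over the list alone (median −0.54, adjusted p = 9.82e-05, adjusted p = 0.0357 with an estimated correlation), and of the 15 WNT targets, 8 were lower and none higher, with 9 lower when adjusted over the list alone. As a group they had a median of −0.54 (adjusted p = 1.32e-04, adjusted p = 0.1 with an estimated correlation). SP5 fell by 4.91 ± 0.30 (adjusted p = 1.14e-05).

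Of the 20 genes of the unfolded protein response list, 15 were higher and none lower at 2 d, with 18 higher when adjusted over the list alone. For the list, the median was 1.25 (adjusted p = 1.27e-12, adjusted p = 0.0445 with an estimated correlation). HYOU1, a chaperone induced by hypoxia, rose by 2.00 ± 0.14 (adjusted p = 2.17e-05) and DNAJC3, an inhibitor of stress kinases, by 2.23 ± 0.16 (adjusted p = 2.20e-05). Of the 27 amino acid stress genes, 16 were higher and none lower, with 17 higher when adjusted over the list alone. Members had a median of 0.78 (adjusted p = 1.50e-10, adjusted p = 0.0234 with an estimated correlation). Of the 29 growth factors, 13 were higher and 1 lower, with 13 and 5 when adjusted over the list alone (median 0.79, adjusted p = 6.28e-04, adjusted p = 0.056 with an estimated correlation), including TGFB1 at 2.61 ± 0.24 (adjusted p = 8.31e-05). Of the 46 extracellular matrix genes, 25 were higher and 7 lower, with 27 and 8 when adjusted over the list alone (median 0.64, adjusted p = 4.89e-05, adjusted p = 0.323 with an estimated correlation), including COL12A1 at 3.99 ± 0.33 (adjusted p = 5.03e-05) and LOXL2, a collagen crosslinking enzyme, at 2.38 ± 0.17 (adjusted p = 2.34e-05). PLVAP, a protein of vesicle diaphragms, and the VEGF receptor FLT1 rose by 6.33 ± 0.49 (adjusted p = 4.00e-05) and 4.87 ± 0.36 (adjusted p = 2.90e-05). Of the 10 endothelial genes, 3 were higher and 2 lower, with 5 and 2 when adjusted over the list alone, and the list did not pass (median 0.73, adjusted p = 0.134). Of the 40 ribosomal proteins, which took a larger share of reads in CNO 2 h replicate 1, 7 were lower and none higher, with 32 lower when adjusted over the list alone. Taken over all members, the median was −0.92 (adjusted p = 8.69e-06, adjusted p = 0.485 with an estimated correlation).

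The edgeR test called 9187 genes without CNO 2 h replicate 1, 2917, 2980 and 2810 without CNO 2 d replicates 1, 2 and 3, and 683 with all 18 libraries in one fit, in which FOS (adjusted p = 0.103) and FLT1 (adjusted p = 0.111) missed the threshold.

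Of the 16657 genes tested at both times against the shared controls, 333 were called in the same direction at 2 h and 2 d, 303 higher and 30 lower, and 24 in opposite directions. Independent lists of these sizes would share 123. The highest number in 100 simulated draws of unchanged groups, with simulated controls shared by both comparisons, was 0. That is chance without any effect and does not measure how much of the overlap comes from the shared controls. The log2 fold changes of the 2 comparisons correlated across genes at 0.482 (Pearson), where the simulated median was 0.331, and their covariance was 0.251 against 0.0170 simulated. Part of the excess may come from the shared controls, since 3 libraries cannot be split with at least 2 in each part. The number of shared genes was 2347, 221 and 219 without CNO 2 h replicates 1, 2 and 3, and 137, 140 and 132 without Astrostim replicates 1, 2 and 3.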

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

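The 3 tests on NPC replicate 3 and the tests of gene length and of a smaller response in CNO 2 h replicate 1 were chosen only after the results were seen. The test of the difference between the CNO effects at 2 d and 2 h, made on 9 libraries in one fit, passed for 4672 genes. Of the 27 genes named for both CNO comparisons, 19 differed between the times, 11 lower and 8 higher at 2 d. The log2 differences, 2 d minus 2 h, were −3.49 for CXCL8, −3.38 for ARC, −2.71 for NR4A1, −2.62 for EGR1, −2.52 for FOS, −1.73 for SOX10, −0.86 for RCAN1, −0.85 for DUSP1, −0.85 for SNAI2, −0.52 for IDI1 and −0.52 for EPHA2. They were 0.66 for NDRG1, 0.94 for CD44, 1.003 for EMP1, 1.13 for CHRM3, 1.15 for ANKRD1, 1.48 for PDGFB, 1.51 for HERPUD1 and 2.13 for PTGS2. The adjusted p-values of the 19 genes ranged from 1.43e-06 (NR4A1) to 0.0379 (IDI1). ARC was the gene among them with effects of opposite sign, 1.82 at 2 h and −1.57 at 2 d. With all 18 libraries in one fit, 2 of the 19 differences, those of ARC and NR4A1, were kept and 17 missed the threshold, with an adjusted p of 0.0684 for EGR1, 0.0901 for CXCL8, 0.103 for FOS, 0.132 for PTGS2, 0.134 for HERPUD1, 0.181 for CHRM3, 0.210 for PDGFB, 0.235 for DUSP1, 0.248 for NDRG1, 0.301 for IDI1, 0.312 for SOX10, 0.390 for EMP1, 0.454 for EPHA2, 0.459 for RCAN1, 0.499 for ANKRD1, 0.555 for SNAI2 and 0.678 for CD44. Without CNO 2 d replicates 1, 2 and 3, the adjusted p was 0.0644, 0.0631 and 0.0739 for CHRM3 (0.0214 with all 9 libraries) and 0.118, 0.114 and 0.0725 for IDI1, and without replicate 1 it was 0.0528 for EMP1. IDI1 also missed the threshold without Astrostim replicates 1, 2 and 3 (adjusted p = 0.0579, 0.0601 and 0.0594), without a filter on low counts (adjusted p = 0.0538) and with the replicate block (adjusted p = 0.0685), and EPHA2 with the gene length and GC correction (adjusted p = 0.115).

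The difference between the CNO times also passed for 11 gene lists that passed at both times. The median log2 differences, 2 d minus 2 h, were −1.75 for immediate early genes, −0.92 for ribosomal proteins, −0.70 for targets of calcium-NFAT and CREB signalling, −0.67 for neural crest and Schwann cell genes, −0.57 for NF-kB targets and −0.46 for voltage-gated channels. They were 0.51 for pan-reactive astrocyte genes, 0.68 for heat shock genes, 0.78 for amino acid stress genes, 0.79 for growth and neurotrophic factors and 1.25 for endoplasmic reticulum chaperones. These medians are over the differences of single genes, and against the controls the medians were 1.32 at 2 h and 1.36 at 2 d for calcium-NFAT and CREB targets and 1.49 and 1.61 for NF-kB targets, not lower at 2 d. Ribosomal proteins had medians of 0.61 at 2 h and −0.34 at 2 d, and the first of these came from CNO 2 h replicate 1 (1.37, against −0.06 and 0.04 in replicates 2 and 3). With an estimated correlation, 3 of the 11 kept their call: immediate early genes (adjusted p = 0.0108), amino acid stress genes (adjusted p = 0.0234) and endoplasmic reticulum chaperones (adjusted p = 0.0445). With an estimated correlation the adjusted p was 0.0560 for growth and neurotrophic factors, 0.115 for NF-kB targets, 0.128 for calcium-NFAT and CREB targets, 0.142 for pan-reactive genes, 0.148 for neural crest genes, 0.161 for heat shock genes, 0.426 for voltage-gated channels and 0.485 for ribosomal proteins, which also missed the threshold with fry (adjusted p = 0.109). Pan-reactive genes missed it without a filter on low counts (adjusted p = 0.0606) and with the stricter filter (adjusted p = 0.101), and neural crest genes with the replicate block (adjusted p = 0.0564). Single libraries ended several of these calls too. Without CNO 2 h replicate 2 the adjusted p was 0.0968 for voltage-gated channels, 0.0638 for neural crest genes and 0.0638 for pan-reactive genes, and without CNO 2 h replicate 3 it was 0.0559 for voltage-gated channels, 0.0639 for neural crest genes and 0.0559 for calcium-NFAT and CREB targets. Neural crest genes also missed the threshold without Astrostim replicates 1, 2 and 3 (adjusted p = 0.0547, 0.0510 and 0.0502).

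NPC replicate 3 carried POU5F1, the pluripotency factor OCT4, at 2444 CPM, a gene chosen after its values were seen, and 15 of 16 pluripotency genes above 10 CPM. A minority of undifferentiated cells in a culture otherwise like NPC replicates 1 and 2 is argued against: 82 of 4360 genes at 50 CPM or more in both of those libraries lay under 10% of their mean in NPC replicate 3. For scale, on other sets of genes, those at 50 CPM or more in replicate 2 held 0 under 10% of that level in replicate 1. Those at 50 CPM or more in replicate 1 held 8 under 10% of that level in replicate 2. An exchange of labels with a library of another group is argued against too, because the highest POU5F1 level in the 15 libraries of other groups was 0.0434% of that in NPC replicate 3. A largely undifferentiated culture, or a library from outside the groups, stays open, since progenitor genes had a median of 48.2% of their mean in the other NPC libraries, between the bounds set for and against it. The 19 progenitor genes used ranged widely, from 1.29 to 710% of that mean, and 3 of them lay under 10%. Beyond these states of the culture, no biological explanation was tested, and the count of genes changed in iAstros against NPCs was 293 without this library.

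CNO 2 h replicate 1 lay apart from CNO 2 h replicates 2 and 3. Its deviation from replicates 2 and 3 was set against gene length over 4998 genes. These had a high unadjusted p after CNO for 2 h in the edgeR fit without replicate 1, which does not show that they do not respond. The deviation fell with gene length (Spearman rho −0.347 across genes, which are not independent replicates), where the highest absolute value in the other 8 Astrostim libraries was 0.124. A gene length trend such as a difference in RNA integrity or library preparation may account for the distance of replicate 1. For a trend on GC content, rho within genes of like length was 0.158, and its absolute value reached 0.293 in another library. A rank correlation does not measure the size of a trend, and the deviations of replicate 1 were larger. This test therefore cannot decide whether GC content contributed. The immediate early genes had a median log2 change of 3.35 in replicate 1 and of 3.46 and 3.58 in replicates 2 and 3. In the same order, the medians were 1.97, 1.78 and 1.65 for MAP kinase feedback genes and 1.64, 1.27 and 1.30 for calcium-NFAT and CREB targets. They were 2.34, 2.10 and 1.70 for cytokine and chemokine genes and 1.90, 1.62 and 1.69 for NF-kB targets. Contractile genes and targets of YAP and SRF had medians of 1.48, 1.42 and 1.62. These values carry the length trend: replicate 1 deviated by a median of 0.62 in genes of 1 to 2 kb and of −0.52 in genes of 8 to 16 kb. The lengths of the genes of these lists were not allowed for, so a smaller response to CNO stays open. Beyond that response, no biological explanation was tested, since the labels set this library apart in nothing, and 403 of the 416 genes called after CNO for 2 h were kept among 629 with a correction for gene length and GC content.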

How the results depend on the processing

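The correction for gene length and GC content and the block in DESeq2 and limma-voom were chosen only after the data were seen. In iAstros against NPCs, 72 genes passed, 205 without a filter on low counts, 137 with the stricter filter, 1972 with DESeq2, 4572 with all 18 libraries in one fit, and 0 with edgeR and the replicate block (3399 at an unadjusted p under 0.05), against 2206 with DESeq2 and 151 with limma-voom under that block. Leaving out libraries gave 0 (without iAstro replicate 1, with 1977 at an unadjusted p under 0.05 in edgeR) to 293 (without NPC replicate 3). In OptoNeurons against iAstros, leaving out libraries moved the 8465 genes to between 5537 and 10233. After CNO for 2 h, 905 genes passed with DESeq2, 214 with the replicate block, 155 with all 18 libraries in one fit, 629 with the length and GC correction (539 higher and 90 lower, with 403 of the 416 kept), and 157 to 3336 with a library left out. After CNO for 2 d, 974 passed with all 18 libraries in one fit and 2931 at an absolute log2 fold change of at least 1, and 9948 to 10387 with a library left out. Between the CNO times, 683 passed with all 18 libraries, 2238 at an absolute log2 fold change of at least 1, 2810 to 9187 with a library left out, and 5577 with the length and GC correction. There were 333 shared calls, and DESeq2 gave 687, the replicate block 182, an absolute log2 fold change of at least 1 gave 207, and leaving out a library 132 to 2347. Fewer genes passing at a minimum fold change follows from its construction, and the cause of the other changes was not tested. The fit of all 18 libraries shares one estimate of the spread among groups whose spread differs, with a biological coefficient of variation of 0.552 in iAstros against NPCs and 0.0571 after CNO for 2 d.

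With an estimated correlation, camera passed 0 lists in iAstros against NPCs, OptoNeurons against iAstros and CNO for 2 d, 6 after CNO for 2 h and 4 between the CNO times; fry passed 2 in iAstros against NPCs, 34, 22 and 45 in the next 3 comparisons and 37 between the CNO times. With a library left out, 24 to 30, 31 to 34, 19 to 25, 30 to 34 and 18 to 28 lists passed in the 5 comparisons. The direction reversed for nuclear oxidative phosphorylation genes after CNO for 2 h, with adjusted p between 3.47e-06 (without CNO 2 h replicate 2) and 0.982 (without replicate 1, reversed), and for ribosomal proteins, between 5.48e-08 (without replicate 2) and 0.578 (without replicate 1, reversed). No other list or named gene reversed. Of the values of named genes under settings other than leaving out a library, 259 of 330, 1099 of 1111, 460 of 506, 1012 of 1103 and 805 of 874 kept their side of the threshold in the 5 comparisons, and with a library left out 127 of 222, 934 of 960, 306 of 384, 945 of 948 and 958 of 990 did.

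The replicate numbers did not pair the samples outside iAstros against NPCs: the correlations of same-numbered samples ranged from −0.119 to 0.0438, and not every sample correlated best with its own number. The block then called 6833 genes in OptoNeurons against iAstros and changed the counts after CNO for 2 h and of shared calls as given. In iAstros against NPCs, 27 lists passed with the block and 25 without, all 25 of them kept, and among the genes and lists named there the block in edgeR and camera changed no other call than those given beside them. A pseudocount and edgeR on recovered reads were not run, since the files hold counts. At 14093399 to 23063491 reads, a gene with 0 counts in a library is limited to 3 counts of that total.

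The 6 libraries of a pair of groups can be split in 10 ways, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes, and the highest of the others was 0 by edgeR's quasi-likelihood test: the real counts were 72, 8465, 416, 10739 and 4672. In iAstros against NPCs, the highest of the other splits that part 3 pairs was also 0.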

Other observations

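No test in this part was chosen after a result was seen, since it reports levels and planned tests alone, and the genes named for their levels were chosen after their values were seen. Levels of iAstros and Astrostim cells are set side by side without a test, because day and receptor differ between these groups. The groups come from different tables, whose counts were joined and then put on one scale. S100B averaged 243 ± 145 CPM in iAstros and 19.5 ± 2.25 CPM in Astrostim cells without CNO (SD, n = 3), CD44 averaged 303 and 1.92 CPM, and AQP4 averaged 55.6 and 0.0930 CPM. SLC1A3 averaged 132 ± 53.2 CPM in iAstros and 100 ± 3.95 CPM in Astrostim cells, and SOX9 averaged 607 ± 245 and 740 ± 28.0 CPM. GFAP ranged from 2.33 to 31.5 CPM in iAstros and from 0.159 to 0.525 CPM in Astrostim cells. ALX4 averaged 214 CPM in Astrostim cells and 0.860 CPM in iAstros, TWIST1 averaged 147 and 3.83 CPM, and COL1A1 averaged 90.1 ± 20.9 and 3785 ± 5567 CPM. TFAP2B, a neural crest factor, averaged 383 ± 18.3 CPM in Astrostim cells and 46.4 ± 27.3 CPM in iAstros. High levels of these factors were not particular to Astrostim cells. In the NPC libraries ALX4 ranged from 0.315 to 117 CPM, TWIST1 from 0.944 to 127 CPM and TFAP2B from 0.189 to 327 CPM. The progenitor factor SOX1 averaged 0.527 CPM in NPCs. OLIG2, a factor of the oligodendrocyte and motor neuron lineages, averaged 49.6 ± 4.85 CPM in Astrostim cells and 1.41 CPM in iAstros. STMN2, a neuronal microtubule regulator, averaged 623 ± 26.5 CPM in Astrostim cells, 155 ± 155 CPM in iAstros and 3106 CPM in OptoNeurons. FOS lay between 84.1 and 567 CPM in the iAstro libraries and averaged 1.31 CPM in Astrostim cells.

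Further gene groups moved in the comparisons. In OptoNeurons against iAstros, 22 of 31 nuclear genes of oxidative phosphorylation rose and none fell, with 24 higher when adjusted over the list alone (median 0.86, adjusted p = 1.28e-07, adjusted p = 0.441 with an estimated correlation), including CYCS, the electron carrier cytochrome c, at 1.51 ± 0.15 (adjusted p = 7.90e-04). After CNO for 2 h, 5 of 25 cholesterol synthesis genes rose and none fell, with 8 higher when adjusted over the list alone (median 0.51, adjusted p = 1.85e-07, adjusted p = 0.0326 with an estimated correlation), among them INSIG1, a sensor of sterol levels, at 1.36 ± 0.12 (adjusted p = 0.0017). The median of this list was 0.84 in CNO 2 h replicate 1 and 0.32 and 0.28 in replicates 2 and 3. After CNO for 2 d, 20 of 21 contractile genes and targets of YAP and SRF rose and none fell (median 1.43, adjusted p = 1.33e-12, adjusted p = 0.165 with an estimated correlation). ANKRD1, a target of YAP, rose by 4.95 ± 0.13 (adjusted p = 9.31e-22). Of 13 cilia genes, 10 fell and 1 rose at 2 d (median −1.25, adjusted p = 0.00278, adjusted p = 0.105 with an estimated correlation).

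The iAstro libraries differed from each other in genes of other cell types. COL1A1 ranged from 105 to 10189 CPM and KRT7, an epithelial keratin, from 1.32 to 219 CPM, and NEUROG2 reached 25.3 CPM. Scaled within the comparison with NPCs, replicates 1, 2 and 3 had GFAP at 30.6, 2.30 and 25.6 CPM and CD44 at 493, 31.4 and 349 CPM. DCX lay at 164, 510 and 59.5 CPM, SLC17A6 at 7.28, 31.2 and 1.19 CPM and SOX1 at 57.6, 217 and 15.6 CPM. Not all astrocyte genes were low in replicate 2, with SLC1A3 at 129, 183 and 74.0 CPM and MLC1 at 25.4, 38.9 and 7.77 CPM. Spearman correlations across genes between the iAstro libraries in the table with the NPCs were 0.942 (replicates 1 and 2), 0.955 (1 and 3) and 0.877 (2 and 3). In NPC replicate 3, SOX9 lay at 21.9 CPM, against 341 and 313 CPM in NPC replicates 1 and 2, and SOX2 at 310 CPM, against 26.7 and 43.8 CPM. The epithelial cadherin gene CDH1 lay at 108, 0.827 and 654 CPM in NPC replicates 1, 2 and 3.

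At an adjusted p under 0.05, the authors' deposited table called 1733 genes in iAstros against NPCs (1203 higher and 530 lower), 9747 in OptoNeurons against iAstros, 744 after CNO for 2 h and 9439 after CNO for 2 d. Of the genes called here, 72 of 72, 8196 of 8465, 415 of 416 and 9094 of 10739 were also called in the authors' deposited table with the same direction, and 0 with the opposite direction.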
